A study of Arabidopsis thaliana with 3 samples.

How the data were processed

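Chromatin immunoprecipitation followed by hybridisation to a tiling array (ChIP-chip) was measured on 3 arrays, each for 1 biological replicate of Arabidopsis thaliana seeds that over-express myc-tagged PIL5. PIL5, also called PIF1, is a basic helix-loop-helix protein that binds phytochrome and holds back seed germination. Per the labels' protocols, the seeds received far-red light at 3.2 μmol m-2 s-1 for 5 min and were then kept in the dark for 6 h. DNA was amplified by ligation-mediated PCR per the series' design text, and 500 ng of it was labelled with Cy3 or Cy5 per the labels' protocols. Each array carried precipitated DNA in one colour and input DNA, taken before precipitation, in the other. Untagged seeds and precipitations without antibody were not analysed here.

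The deposited scanner files hold the intensity of every probe on a linear scale, at 532 nm and at 635 nm, written by NimbleScan 2.3.78 per the file headers. No background correction or scaling of these intensities is given in the sources used here, and they were used as deposited. The deposited ratios come as a log2 value per probe and array. They differed from the log2 ratio of the scanner intensities by a constant on each array, to within 0.005, so the deposited ratios are unscaled log2 ratios centred near 0 (column medians 0, 0 and 0.01). The array design held 385991 genomic probes, 124253 on chromosome 4 from position 6133109 to 18584874 and 261738 on chromosome 5 from 1 to 26992645, at a median spacing of 90 bp, and 3316 random probes. The other chromosomes were not analysed here.

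The direction of the ratio needed a decision. The labels give Cy5, read at 635 nm, to the precipitated DNA on all 3 arrays. The deposited ratio runs as 635 nm over 532 nm for replicates 1 and 2 and as 532 nm over 635 nm for replicate 3. With the 635 nm channel on top throughout, replicate 3 correlated with replicate 1 at r = -0.476 and with replicate 2 at r = -0.420 across probes. The 635 nm channel of replicate 3 had a Spearman correlation of 0.966 with the input of replicate 1 and 0.925 with the input of replicate 2, against 0.828 and 0.818 with their precipitated DNA. The direction of the deposited ratio was therefore followed, and the labels' direction was run as an alternative. The direction on replicates 1 and 2 rests on both the labels and the deposited table, and on replicate 3 on the deposited table and the values.

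Log2(precipitated/input) was computed per probe and centred on the median of each array, with no loess or quantile step. A window was the mean of all genomic probes within 300 bp of a probe, with at least 3 probes. The 384765 windows were tested against 0 over the 3 arrays with limma 3.58.1 (lmFit with an intercept, eBayes; two-sided) in R 4.3.3 (data.table package, version 1.17.8), and p-values were adjusted by Benjamini-Hochberg. A window was enriched at an adjusted p under 0.05, a mean log2 ratio of at least 0.58 (1.49-fold) and a ratio above 0 on all 3 arrays. Enriched windows within 300 bp were merged into a region, whose height is that of its highest window, the summit. Picking the highest window raises that height by chance. Mirror-image regions, depleted in precipitated DNA, were called the same way as a planned measure of background, since immunoprecipitation is not designed to deplete sites. Because they lay mostly inside genes, unlike enriched regions, they do not count false enriched regions between genes. The number of arrays limits the precision.

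The files name no genome build for the array positions. Gene names, gene neighbours and gene spans came from a RefSeq gene table of assembly TAIR10.1. Its fit to the array was tested on the data: input brightness was set against protein-coding gene spans at lags of up to 30000 bp in segments of 500000 bp. On the tiled part of chromosome 4 (26 segments) and on chromosome 5 up to position 9999999 (20 segments) the best lag lay within 90 bp of 0. In 27 segments of chromosome 5 from 13500000 on, the median best lag was -17240 bp. Gene names were therefore given only in the first 2 stretches, 224203 probes or 58.1% of all, called the annotated part. Regions elsewhere are given by array position alone, and no position was converted. Coordinates printed are the array's, 1-based. The gene table gives no strand, so the planned promoter of 1000 bp upstream of a gene start was replaced by the 1000 bp flank on each side of a gene span, and a flank at the start of a gene cannot be told from one at its end. Only the protein-coding genes of the gene table were used, so genes of other kinds count as space between genes. Exons, introns and UTRs were not used here.

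A gene was called bound when an enriched region overlapped either flank. The place of region summits was tested by shifting them circularly along the tiled windows 10000 times (two-sided permutation test). The mean ratio of each flank with at least 3 probes was also tested with limma (12145 flanks of 6083 protein-coding genes). Of 202 genes in 9 lists fixed before the data were examined, 54 lay in the annotated part. The 8 lists with at least 3 such members were tested for bound members with Fisher's exact test and for a shift of flank ratios with limma's camera (preset correlation 0.01, and an estimated correlation), each adjusted over the 8 lists. The design, tests and most alternatives were also fixed before the data were examined. Genes and regions were named by a fixed rule: the 20 regions with the highest mean log2 ratio, named by their neighbouring genes, and from each list up to 4 bound members with the highest regions and up to 2 members without one with the highest flank mean. GAI, RGA, SOM and the PIL5 locus were also to be named, but none lies on the tiled chromosome parts. A planned search for the G-box and other motifs, and a correction for probe base composition, were not run, since no genome or probe sequence was used here.

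The steps were tested on simulated data. Arrays rotated against each other along the tiling, with blocks 600 bp long added at 200 places, gave no region outside the added blocks among 384765 windows. Rotation removes probe effects that the arrays share, so it does not measure false regions from such effects. Blocks of 0.75, 1, 1.5 and 2.5 log2 units were recovered in 0%, 0%, 32.0% and 98.0% of 50 cases each. With few true sites the adjusted threshold is stricter than on the real arrays. For flanks, the same heights were recovered in 16.0%, 38.0%, 98.0% and 100% of 50 cases among 12145. For the place of summits, 4% of 200 random sets had a p under 0.05, and all 50 sets with added summits outside genes did. Alternatives covered scaling, background, dim probes, window width and probe minimum, height and p thresholds, another null, flank length and leaving out each array. Plots were made with matplotlib 3.10.9 in Python 3.11.15.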

Results

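The series asked which sites of the seed genome are bound directly by PIL5. Precipitated DNA was compared with input DNA on each of 3 arrays, 1 per biological replicate, all in 1 group. The median intensity of the 385991 genomic probes was 3825, 5507 and 6028 for the input of replicates 1, 2 and 3, and 3433, 4646 and 4900 for the precipitated DNA. Random probes had medians between 244 and 336, so genomic probes were 14.1 to 20.7 times brighter. Ratios of different replicates correlated at r = 0.405 (replicates 1 and 2), 0.476 (1 and 3) and 0.420 (2 and 3) across probes, with Spearman values of 0.328, 0.403 and 0.343. Across windows Pearson's r was 0.468, 0.502 and 0.50. Probes and windows are not independent replicates, and no test was run on these correlations.

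PIL5-myc precipitates were enriched at 3463 regions on the tiled parts of chromosomes 4 and 5. The median region was 451 bp wide and 1.89-fold enriched at its summit, and the highest was 10.9-fold enriched. Chromosome 4 held 1211 regions and chromosome 5 held 2252. With the minimum raised to 2-fold, 1530 regions were called, and at 4-fold 190. The mirror-image threshold gave 1716 depleted regions, 49.6% of the enriched count, at the lowest minimum. With input brightness subtracted there were 895 depleted against 2837 enriched regions, and with a null taken from the mirror-image tail 161 against 1674. Depleted regions numbered 178 at 2-fold, 1 at a log2 ratio of 1.5 (against 564 enriched) and 0 at 4-fold by limma, among 91230 windows with an unadjusted p under 0.05 in either direction. Ratios are given in the direction of the deposited ratio table. With the labels' dyes on replicate 3, limma called 0 enriched and 0 depleted regions, with 3893 windows at an unadjusted p under 0.05, and the mirror-image null called 16 and 2. With every array's sign turned, the 2 counts change places, so the depleted count is also the enriched count in that direction. Without replicate 3 there were 1652 enriched and 730 depleted regions, while the median log2 ratio at the 3463 summits was 0.84 against 0.92 on all arrays.

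**Figure D1:**
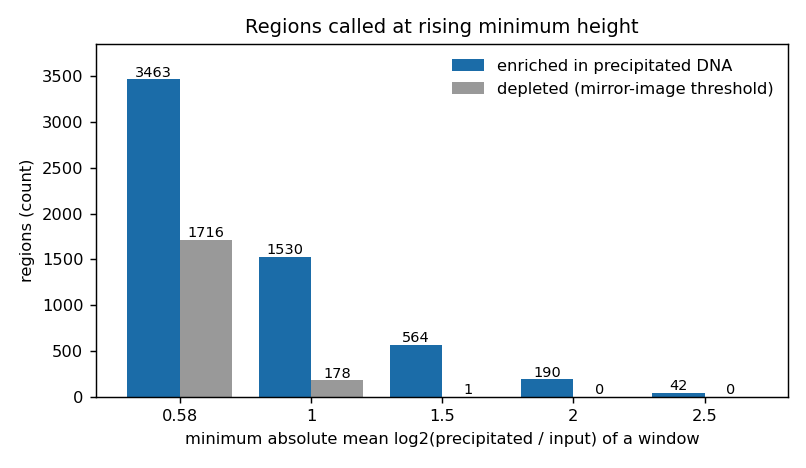
Number of regions (vertical axis, count) called at each minimum absolute mean log2 ratio of a window (horizontal axis), enriched in blue and depleted by the mirror-image threshold in grey. Enriched regions fall from 3463 to 42 over the minimums shown, and depleted regions from 1716 to 0.

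Region density was uneven along the chromosomes. Per 1000 probes, the last Mb of chromosome 5 held 16.5 enriched regions, its first Mb 13.1 and the stretch from Mb 11 to 14 held 2.44, against 8.74 in the rest of the chromosome. On chromosome 4 the stretch from Mb 17 to the end of the tiling held 15.2 against 8.94 elsewhere. Depleted regions varied less, with 3.95, 5.28, 2.40 and 4.56 per 1000 probes in the same parts of chromosome 5. No test was run on these densities, and the parts were chosen after the values were seen.

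**Figure D2:**
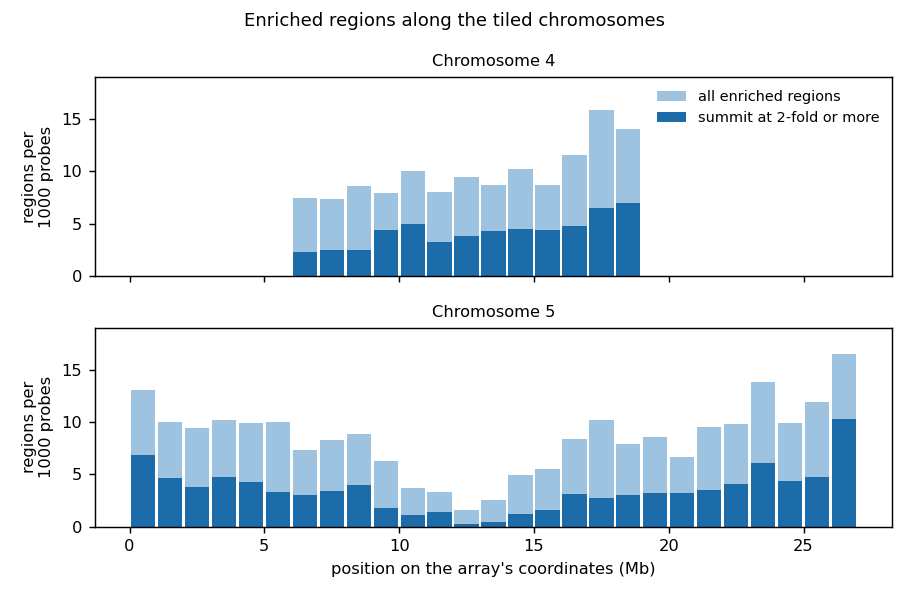
Enriched regions per 1000 probes (vertical axis) in bins of 1 Mb along the array positions of chromosomes 4 and 5 (horizontal axis, Mb). Light bars show all enriched regions and dark bars those with a summit at 2-fold or more; the last bin of chromosome 5 stands at 16.5.

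The 20 highest regions were 6.70-fold to 10.9-fold enriched, and the lowest log2 ratio of any of them on any array was 2.21. Of these, 8 summits lay between genes, 3 lay inside a gene span and 9 lay in the part of chromosome 5 without gene names. A region on chromosome 5 from 2613516 to 2615496 was enriched 8.88-fold (log2 ratio 3.15 ± 0.34, SD, n = 3; limma adjusted p = 7.21e-06) in the 5.9 kb between AT5G08139 and BIM1 (AT5G08130), a basic helix-loop-helix protein of brassinosteroid signalling. On chromosome 4, a region from 9441660 to 9446533 was enriched 7.21-fold (2.85 ± 0.56) in the 11.9 kb between AT4G16770 and HB-2 (AT4G16780). HB-2 is a homeodomain-leucine zipper gene known for its induction by shade. This region did not reach the 1000 bp flank of HB-2. The region by which HB-2 was bound had its summit inside the gene and was enriched 2.51-fold (1.33 ± 0.34). Of the 20 highest, another region on chromosome 4, from 12536288 to 12537009, had its summit inside GRF8 (AT4G24150), a growth-regulating transcription factor. It was enriched 8.77-fold (3.13 ± 0.13), from a window of 3 probes. The transcription factor gene WRKY7 (AT4G24240) held a summit enriched 7.93-fold (2.99 ± 0.27), and CSLA02 (AT5G22740), a glucomannan synthase, held one enriched 6.94-fold (2.79 ± 0.15).

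The other 6 of the highest regions with summits between named genes were 6.70-fold to 8.29-fold enriched. The space between MIPS1 (AT4G39800), which makes inositol phosphate, and AT4G39810 held the summit of a region enriched 7.79-fold (log2 ratio 2.96 ± 0.23, SD, n = 3). Next to AMT1;1 (AT4G13510), an ammonium transporter, and SMAP1 (AT4G13520) the ratio was 6.70-fold (2.74 ± 0.35). Between AT4G28240 and EXPB3 (AT4G28250), an expansin, it was 6.79-fold (2.76 ± 0.22), and between AT4G22000 and sks4 (AT4G22010) it was 6.80-fold (2.77 ± 0.20). The region with its summit between AT5G01720 and SCAR4 (AT5G01730), a regulator of actin nucleation, was enriched 8.29-fold (3.05 ± 0.35). The one between FLP1 (AT4G31380) and ACDO1 (AT4G31390) was enriched 8.28-fold (3.05 ± 0.13). The regions at EXPB3 and SCAR4 were 2176 and 2310 bp wide. The spaces around their summits were 1 and 2.2 kb long, so both regions ran into gene spans. Of the 20 regions, the highest without gene names ran from 25453350 to 25454430 on chromosome 5. It was enriched 10.9-fold (3.45 ± 0.08), from a window of 3 probes. The next, from 26588132 to 26592182, was enriched 9.04-fold (3.18 ± 0.40). All 20 had limma adjusted p-values of at most 1.18e-05 and a ratio above 0 on all 3 arrays. All 20 lost the call with the labels' dyes on replicate 3.

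**Figure D3:**
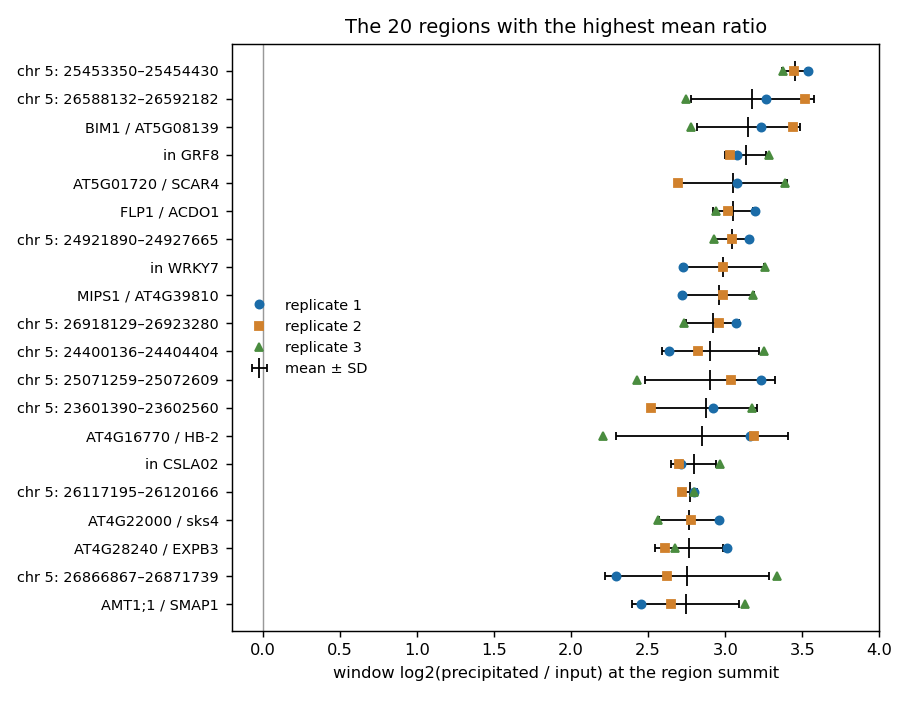
Log2 ratio of precipitated over input DNA at the summit window (horizontal axis) of the 20 regions with the highest mean, named by neighbouring genes or by array position. Symbols show replicates 1, 2 and 3, and bars the mean ± SD; every array lies at 2.21 or higher.

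Summits of enriched regions lay mainly between protein-coding genes. Of 2146 summits in the annotated part, 66.7% lay outside gene spans (1431; exact 95% binomial interval 64.6 to 68.7), against 31.2% for summits shifted along the tiling (95% of shifts between 29.0 and 33.5; permutation p = 1e-04, the smallest that 10000 shifts can give). Within 1000 bp of a gene span and outside genes lay 49.3%, against 20.2% for shifted summits (permutation p = 1e-04). Summits at 2-fold or more had a like share outside genes, 66.6% of 921. Depleted regions had the opposite place: 94.4% of 1084 summits lay inside gene spans, against 68.9% when shifted (permutation p = 1e-04). The depleted counts and the mirror-image null therefore cannot be read as the number of false enriched regions between genes. Over the 6 shares tested the Benjamini-Hochberg values were also 1e-04. Binomial intervals cover counting error only. The log2 ratio of all probes outside genes exceeded that of probes inside by 0.31, 0.25 and 0.29 at the median of replicates 1, 2 and 3. With probes inside and outside genes centred separately, 47.0% of summits lay outside genes.

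**Figure D4:**
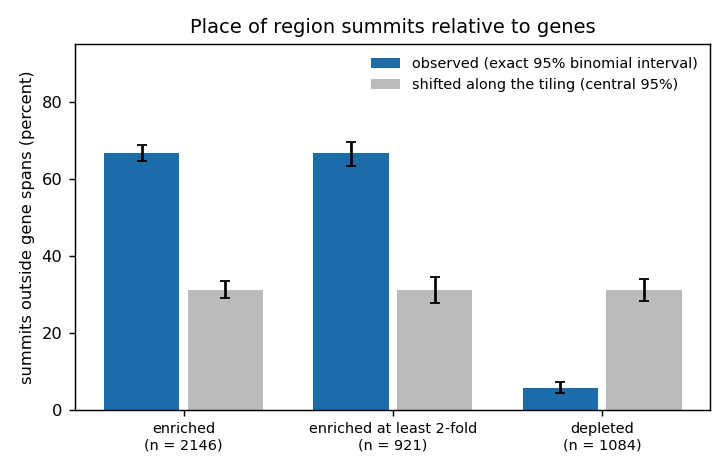
Percent of region summits outside gene spans (vertical axis) for enriched regions, enriched regions at 2-fold or more, and depleted regions in the annotated part. Blue bars show the observed share with its exact 95% binomial interval, and grey bars the mean of 10000 circular shifts with the central 95% of shifts; the observed shares are 66.7%, 66.6% and 5.63%.

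Of the 6083 protein-coding genes in the annotated part, 2169 (35.7%) were bound, 1152 (18.9%) by a region at 2-fold or more and 153 by a region at 4-fold or more. Taking the mean over each whole flank in place of the best window, limma called 1288 genes with an enriched flank and 136 with a depleted flank, 11 of them with both. Without replicate 3, 297 genes had a depleted flank. Below, bound list genes are given by their summit window and genes without a region by the mean of their higher flank. A summit height and a flank mean are unlike measures and do not compare.

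The list tests did not match genes for the length of the spaces around them. Probes outside genes stood 0.25 to 0.31 log2 units above those inside, so a difference in spacing could add to a list's bound share or flank shift. Of 7 genes of brassinosteroid, ethylene and cytokinin action, 6 were bound (85.7%), against 35.6% of the other genes (Fisher's exact test, two-sided, adjusted p = 0.0398). CRF2 (AT4G23750), a cytokinin response factor, had a region on chromosome 4 from 12374971 to 12376501 enriched 3.90-fold (log2 ratio 1.96 ± 0.14, SD, n = 3). The region at CTR1 (AT5G03730), a kinase that holds back ethylene responses, was enriched 3.75-fold (1.91 ± 0.20). BRI1 (AT4G39400), the brassinosteroid receptor, had 3.37-fold (1.75 ± 0.56), with the summit inside the neighbouring PLS. The kinase gene BIN2 (AT4G18710) had 3.14-fold (1.65 ± 0.08), with the summit inside BIN2 itself. CPD, a brassinosteroid synthesis enzyme, had no region, and its higher flank had a log2 ratio of 0.37 (SE 0.15, adjusted p = 0.110). The flanks of this list stood 0.65 log2 units above those of other genes (camera adjusted p = 7.86e-06). That call was lost with an estimated correlation (adjusted p = 0.413) and with the labels' dyes (0.20, adjusted p = 0.129). The Fisher call was lost in 5 of 22 alternatives: with the dimmest 10% of probes left out (adjusted p = 0.123), under normexp (0.0621) and quantile normalization (0.0554), at 5 probes per window (0.0504) and with the labels' dyes (0 bound, adjusted p = 1). By flank means, 6 of its genes were enriched over all flanks tested, and 6 when adjusted over the list alone.

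All 5 abscisic acid genes in the annotated part were bound (Fisher's exact test, adjusted p = 0.0398). PYR1 (AT4G17870), an abscisic acid receptor, had a region from 9928698 to 9930699 on chromosome 4 enriched 3.33-fold (log2 ratio 1.73 ± 0.61, SD, n = 3). The summit of that region lay inside PYR1. NCED2 (AT4G18350), of the family that cleaves carotenoids in abscisic acid synthesis, had 2.08-fold (1.05 ± 0.40). The phosphatase gene ABI1 (AT4G26080) had 1.84-fold (0.88 ± 0.17), and CYP707A1 (AT4G19230), which inactivates the hormone, 1.68-fold (0.74 ± 0.18) from a window of 3 probes. The Fisher call did not hold without replicate 2 (3 bound, adjusted p = 0.568) or without replicate 3 (2 bound, adjusted p = 0.369), nor at a minimum of 2-fold (2 bound, adjusted p = 0.512), and was lost in 17 of 22 alternatives in all. Without replicate 3 the regions at ABI1 and CYP707A1 had log2 ratios of 0.87 and 0.66 with adjusted p-values of 0.0552 and 0.132. CYP707A1 also lost its call without replicate 2 (0.74, adjusted p = 0.0593) and with separate centring (0.64, adjusted p = 0.0518). The flank shift of 0.31 (camera adjusted p = 0.0318) was lost with an estimated correlation (adjusted p = 0.413) and without replicate 1 (0.26, adjusted p = 0.0828), and in 6 of 14 alternatives in all. By flank means, 3 genes were enriched over all flanks tested and 3 when adjusted over the list alone.

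Of 7 gibberellin genes, 4 were bound, which did not pass Fisher's exact test (adjusted p = 0.410), and without replicate 3 only 1 was bound (adjusted p = 1). GA20OX3 (AT5G07200), a gibberellin synthesis oxidase, had a region on chromosome 5 from 2239028 to 2243117 enriched 5.74-fold (log2 ratio 2.52 ± 0.39, SD, n = 3; limma adjusted p = 1.23e-05). The region at RGL3 (AT5G17490), a DELLA repressor of gibberellin responses, was enriched 2.97-fold (1.57 ± 0.67) with its summit inside the gene. GA3 (AT5G25900), ent-kaurene oxidase, had 2.17-fold (1.12 ± 0.84), and SLY1 (AT4G24210), an F-box protein that targets DELLA proteins, had 1.77-fold (0.82 ± 0.57) with the summit inside VEP1. Without replicate 3, the log2 ratios were 0.67 at GA3 (adjusted p = 0.155) and 0.54 at SLY1, under the minimum. GA2OX8 and GA20OX1 had no region, with flank log2 ratios of 0.37 (SE 0.17, adjusted p = 0.160) and 0.35 (SE 0.15, adjusted p = 0.124). The flanks stood 0.28 log2 units higher (camera adjusted p = 0.0318), which was lost with an estimated correlation (adjusted p = 0.550), without replicate 3 (0.21, adjusted p = 0.0962) and with separate centring (0.22, adjusted p = 0.102), and turned in sign with the labels' dyes (-0.0076, adjusted p = 0.977). By flank means, 2 genes were enriched over all flanks tested and 2 when adjusted over the list alone.

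Light signalling and clock genes were bound at 6 of 9 members (Fisher's exact test, adjusted p = 0.154). Without replicate 1, 2 or 3 this test passed, with 7, 7 and 6 bound (adjusted p = 0.0189, 0.0493 and 0.0054). FHL (AT5G02200), which carries phytochrome A into the nucleus, had a region on chromosome 5 from 435502 to 437757 enriched 5.51-fold (log2 ratio 2.46 ± 0.32, SD, n = 3; limma adjusted p = 1.18e-05). PRR5 (AT5G24470) and PRR7 (AT5G02810), both pseudo-response regulators of the clock, had 4.31-fold (2.11 ± 0.31) and 2.59-fold (1.37 ± 0.61). The photoreceptor gene PHYD (AT4G16250) had 3.40-fold (1.77 ± 0.14). FAR1 and LAF1 had no region, with flank log2 ratios of 0.46 (SE 0.16, adjusted p = 0.0661) and 0.41 (SE 0.15, adjusted p = 0.0803). The FAR1 flank passed the test under normexp (0.70, adjusted p = 0.0194). The flank shift of the list was 0.27 (camera adjusted p = 0.0331; adjusted p = 0.422 with an estimated correlation), and without replicate 1 it was 0.21 (adjusted p = 0.0828); the call was lost in 5 of 14 alternatives. By flank means, 5 genes were enriched over all flanks tested and 5 when adjusted over the list alone. At a minimum of 2-fold, 5 members were bound (adjusted p = 0.0335). The Fisher test passed in 9 of 22 alternatives in all.

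All 6 members of the seed list in the annotated part were seed storage or oil body genes, and 5 were bound (Fisher's exact test, adjusted p = 0.0647). The tests of this list therefore say nothing about germination or dormancy genes. Without replicate 1 there were 3 bound (adjusted p = 0.531) and without replicate 3 there were 2 (adjusted p = 0.369). CRU3 (AT4G28520), a 12S globulin, had a region on chromosome 4 from 14089255 to 14091865 enriched 4.22-fold (log2 ratio 2.08 ± 0.06, SD, n = 3), with the summit inside the neighbouring NAC074. OLEO1 (AT4G25140), an oil body protein, had 2.21-fold (1.14 ± 0.08). Of the 2S albumin genes, SESA1 (AT4G27140) had 2.01-fold (1.01 ± 0.51) and SESA3 (AT4G27160) 1.70-fold (0.76 ± 0.06), each with the summit inside the gene. SESA4 (AT4G27170), outside the naming rule, was also bound, at 1.64-fold (0.72 ± 0.28). SESA2 had no region and a flank log2 ratio of 0.08 (SE 0.16, adjusted p = 0.790). These 2S albumin genes are neighbours on the chromosome, and Fisher's exact test counts each as a separate gene. Without replicate 3 the log2 ratios at SESA1 and SESA3 were 0.85 and 0.77 (adjusted p = 0.0944 and 0.0810), and without replicate 1 that at SESA3 was 0.73 (adjusted p = 0.0555). The flank shift was 0.25 (camera adjusted p = 0.0539). Each of these tests passed in 3 alternatives, of 22 for bound members and 14 for the shift. By flank means, 3 genes were enriched over all flanks tested and 3 when adjusted over the list alone.

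None of the remaining lists passed either test. For auxin, 2 of 6 members were bound (Fisher's exact test, adjusted p = 1), IAA14 (AT4G14550) at 1.78-fold (log2 ratio 0.83 ± 0.30, SD, n = 3) and IAA1 (AT4G14560) at 1.60-fold (0.67 ± 0.26), both genes of auxin repressors. YUC8 and IAA29 had no region, with flank log2 ratios of 0.49 (SE 0.18, adjusted p = 0.0823) and 0.20 (SE 0.15, adjusted p = 0.403). By the same measure, the mean of the higher flank, the bound IAA14 and IAA1 had 0.70 (limma adjusted p = 0.0067) and 0.28 (adjusted p = 0.2295). IAA1 thus lay below YUC8. The YUC8 flank passed the test without replicate 3 (0.72, adjusted p = 0.0041). For cell wall loosening it was 2 of 8 (adjusted p = 0.823), the expansin gene EXPA9 (AT5G02260) at 2.99-fold (1.58 ± 0.38) and XTH19 (AT4G30290) at 1.71-fold (0.77 ± 0.28). The XTH19 summit lay inside that gene. EXPA2 and XTH24 had flank log2 ratios of 0.56 (SE 0.17, adjusted p = 0.0391, under the minimum of 0.58) and 0.42 (SE 0.15, adjusted p = 0.0819). The EXPA2 flank passed under normexp (0.63, adjusted p = 0.0286) and without replicate 1 (0.69, adjusted p = 0.0160). Without replicate 3 it had 0.36 (adjusted p = 0.223), and the flank on the other side of EXPA2 passed (0.66, adjusted p = 0.0089). For chlorophyll and carotenoid synthesis it was 3 of 5 (adjusted p = 0.474): PSY (AT5G17230), phytoene synthase, at 2.19-fold (1.13 ± 0.26), CHLH (AT5G13630), a magnesium chelatase subunit, at 2.17-fold (1.12 ± 0.43) with the summit inside PDAT, and PDS3 (AT4G14210) at 1.61-fold (0.69 ± 0.35). PORB and CHLI1 had no region, with flank log2 ratios of 0.14 (SE 0.15, adjusted p = 0.564) and -0.11 (SE 0.15, adjusted p = 0.660).

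Without replicate 2 only 1 auxin gene was bound, and without replicate 3 only 1 cell wall gene. The flank shifts of the auxin, cell wall and pigment lists were -0.03, 0.09 and 0.04 (camera adjusted p = 0.962, 0.451 and 0.931). By flank means 1, 1 and 3 of their genes were enriched over all flanks tested, and 1, 1 and 3 when adjusted over the list alone. In none of the 8 lists was a gene depleted at a flank by limma. Without replicate 3, IAA1, XTH19 and PDS3 lost their calls (log2 ratios of 0.56, 0.62 and 0.50), IAA1 and PDS3 did so without replicate 2 (0.65 and 0.71, adjusted p = 0.114 and 0.0803), and IAA14 without replicate 1 (0.66, adjusted p = 0.0949). The region at PDS3 also lost its call under loess, quantile normalization and normexp (0.66, 0.65 and 0.70, adjusted p = 0.0505, 0.0504 and 0.0522). With separate centring IAA1 and PDS3 lay under the minimum (0.47 and 0.48), and with input brightness subtracted IAA1 had 0.59 (adjusted p = 0.0900). Of the housekeeping genes kept for comparison only ACT7 (AT5G09810), an actin, lay in the annotated part. It was bound, at 3.49-fold (log2 ratio 1.80 ± 0.46, SD, n = 3).

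**Figure D5:**
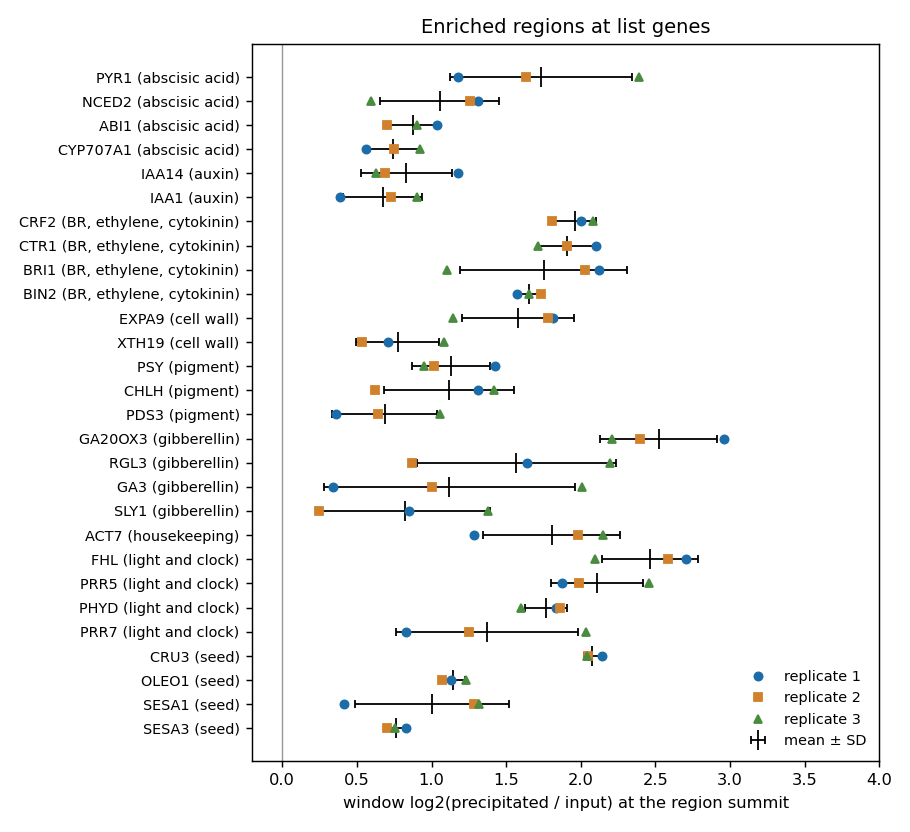
Log2 ratio of precipitated over input DNA at the summit window (horizontal axis) of the enriched regions at the named list genes, with the list in parentheses. Symbols show replicates 1, 2 and 3, and bars the mean ± SD; GA20OX3 stands at 2.52 and FHL at 2.46, a difference smaller than the SD of either.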

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

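For random probes, which match no genomic target by design, only the test of the dye was chosen after the result was seen; the others were fixed before. These probes lay outside the comparisons above, and their signal was higher in precipitated DNA. The 95th percentile of their intensity was 5.85, 2.19 and 5.13 times higher in precipitated than in input DNA on replicates 1, 2 and 3. Their median intensities were close. On the centred scale used for the calls, their median log2 ratios were 0.11, 0.17 and 0.52. Of 3316 random probes, 12.7%, 3.05% and 18.1% had a centred ratio of at least 4-fold, against 0.919%, 0.397% and 1.19% of genomic probes. A dye effect predicted a ratio under 1 on replicate 3, where the deposited table puts the precipitated DNA in the other colour, and the value of 5.13 argues against it. Position on the slide predicted that random probes follow the genomic probes around them, and the highest correlation on any array was 0.0158. The same random probes were high on different arrays (pairwise r of 0.50, 0.683 and 0.452), with 45 at 4-fold or more on all 3 arrays against 2.32 if arrays were independent. Of genomic probes 0.181% (698) were that high on all 3 arrays, against 1.36% of random probes. Material in the precipitated DNA that input lacks, and that these probes capture, may therefore be the source (lowest pairwise r 0.452); what it is was not tested, and no biological explanation was tested. Genomic probes could carry it too, and a high region on 3 probes rests on few of them.

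Leaving out replicate 3 gave 1652 enriched regions, against 3019 and 3555 without replicates 1 and 2, while heights moved less. At the 3463 summits the median log2 ratio was 0.92 on all arrays and 0.84 without replicate 3, where 89.5% still reached the minimum but 43.3% had an adjusted p under 0.05. Limma's prior degrees of freedom were 10.6 there, against 50.1 and 39.8 without replicates 1 and 2, so the 3 counts do not compare the influence of the arrays alone.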

How the results depend on the processing

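The labels' dye direction, the minimum of 1.5, separate centring of probes inside and outside genes and the subtraction of input brightness were chosen after seeing the data. The share of enriched regions outside genes stayed above the shifted share in all 21 alternatives that gave regions (47.0% to 70.7%), as did the share within the flanks (35.1% to 60.4%). Flank lengths of 500 and 2000 bp cannot change the share outside genes, and with no minimum the regions were the same 3463. Enriched regions numbered 3463 and depleted 1716; these became 1530 and 178 at a minimum log2 ratio of 1, 564 and 1 at 1.5, and 1822 and 249 at an adjusted p of 0.01, all stricter by construction. With a null from the mirror-image tail they were 1674 and 161. Without 1 replicate they ranged from 1652 to 3555 and from 730 to 2056. Subtracting input brightness left 895 depleted regions and 89 genes with a depleted flank; the cause was not tested. Genes with an enriched flank fell from 1288 to 846 at 2000 bp flanks. Genes with a depleted flank (136) became 256 with normexp, 240 with no minimum and 59 at 2000 bp. Without 1 replicate they ranged from 176 to 297.

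With the labels' dye direction limma called 0 enriched and 0 depleted regions, with 3893 windows at an unadjusted p under 0.05. The mirror-image null called 16 and 2 regions. By limma, 0 genes had an enriched or depleted flank (90 flanks at an unadjusted p under 0.05). Of the abscisic acid list and the brassinosteroid, ethylene and cytokinin list, 0 members were bound. Flank shifts in this direction were -0.0076 for gibberellin genes, turned in sign, 0.156 for abscisic acid genes and 0.132 for light genes. For the brassinosteroid, ethylene and cytokinin list the shift was 0.201. The log2 ratio turned negative at PDS3 (-0.0193), GA3 (-0.222) and SLY1 (-0.0955); all other named regions lost their call at an adjusted p of 1, most of the 20 highest with a log2 ratio still above the minimum (0.528 to 1.38 over the 20). This setting sets replicate 3 against the others by construction.

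With an estimated correlation the flank shifts of 0.283 (gibberellin), 0.309 (abscisic acid) and 0.270 (light) lost their calls. So did the 0.652 of the brassinosteroid, ethylene and cytokinin list. The estimates, in the same order, were 0.487, 0.0137, 0.0611 and 0.0928, and -0.0223 for seed genes. The preset was 0.01. For abscisic acid and seed genes, camera's unadjusted p still rose, from 0.0119 to 0.1315 and from 0.0337 to 0.1547. Correlated flanks alone therefore do not account for those changes. The gibberellin call was also lost with separate centring (0.217). Abscisic acid lost it at 500 bp (0.236) and 2000 bp flanks (0.224) and with separate centring (0.212), and light at 2000 bp (0.200) and without the dimmest 10% of probes (0.252). Seed genes gained it at 500 bp (0.373), at 2000 bp (0.285) and with brightness subtracted (0.275). Without 1 replicate the shifts ranged from 0.206 to 0.347 (gibberellin), 0.263 to 0.349 (abscisic acid) and 0.210 to 0.302 (light). The gibberellin call was lost without replicate 3 (adjusted p = 0.0962), and those of abscisic acid and light without replicate 1 (adjusted p = 0.0828 for both).

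Bound abscisic acid genes lost the Fisher call with 5 bound (quantile, normexp, 2000 bp flanks), 4 (dim probes left out, windows of 600 bp on each side, 5 probes per window, 500 bp flanks, separate centring, brightness subtracted), 3 (150 bp windows, adjusted p of 0.01), 2 (minimum of 1, mirror-image null) and 1 (minimum of 1.5), and ranged from 2 to 5 without 1 replicate. The brassinosteroid, ethylene and cytokinin list lost the Fisher call with 6 bound in 4 settings (adjusted p = 0.0504 to 0.123). These were quantile, normexp, dim probes left out and 5 probes per window. Light genes gained it with 7 bound (loess), 6 (median of probes, adjusted p of 0.01), 5 (minimum of 1, mirror-image null) and 3 (minimum of 1.5), and with 6 to 7 without 1 replicate. Seed genes gained it with 5 (500 bp flanks, brightness subtracted) and 6 (2000 bp flanks). Without 1 replicate, bound gibberellin genes ranged from 1 to 5 and bound seed genes from 2 to 4, with no call. The causes were not tested.

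Of 48 named regions, 47 or more kept their call under loess, quantile normalization, normexp and the deposited ratio table, 46, 45 and 39 did without replicate 1, 2 or 3, and 45 with separate centring. No paired analysis was possible because there is a single group of arrays, each already set against its own input. The correction for probe base composition and the motif search were not run. Genomic probes lay 14.1 to 20.7 times above random probes at the median, but only 56.5% to 85.2% of them exceeded the 95th percentile of random probes in precipitated DNA.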

Other observations

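The widest region spanned 9803 bp of chromosome 5 from 26260958 to 26270760 (5.36-fold, log2 ratio 2.42 ± 0.10, SD, n = 3). The next widest spanned 6496 bp of chromosome 4 from 10712266 to 10718761 (4.73-fold, 2.24 ± 0.14). Its summit lay between IRT1, the root iron transporter, and the neighbouring AT4G19700.

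Among genes grouped by the stem of their symbol, a grouping chosen after the values were seen, 24 families with at least 8 members in the annotated part were tested for regions at 2-fold or more against genes with flanking spaces of like length (two-sided test by drawing 10000 matched sets). None passed after Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05. Homeobox genes named HB had 5 of 8 members bound at 2-fold or more against 1.78 expected (p = 0.0149, adjusted p = 0.179, Fisher's exact test adjusted p = 0.166). They were HB22 at 6.46-fold (log2 ratio 2.69 ± 0.25, SD, n = 3), HB16 at 4.93-fold (2.303 ± 0.20), HB-8 at 2.99-fold (1.58 ± 0.11), HB-3 at 2.69-fold (1.43 ± 0.29) and HB-2 at 2.51-fold (1.33 ± 0.34). The HB-2 value is from a region apart from the 7.21-fold one, with its summit inside that gene. HB30 was bound at a lower height, 1.71-fold (0.77 ± 0.28). LCR genes, which encode small cysteine-rich proteins, had 0 of 22 bound at 2-fold against 4.61 expected (permutation p = 0.0140, adjusted p = 0.179), and 2 were bound at a lower height. HY5 (AT5G11260), a light-response transcription factor, lay outside the naming rule and was picked out after its value was seen. It had a region enriched 2.21-fold (1.14 ± 0.45). HY5 and HB-2 are members of the light list and are already counted among its bound genes.

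For the place of enriched regions outside genes, the 3 tests below were chosen after the data were seen, each before its own result. A constant offset between probes inside and outside genes predicted that the share of 66.7% would fall into the shifted range once the 2 kinds of probe were centred separately. It fell to 47.0%, above the upper end of that range (33.8%), which argues against the offset as the whole cause but leaves it part of the excess. Probe brightness predicted the same after its trend was subtracted, and the share stayed at 61.7% (upper end 33.8%). Regions at a log2 ratio of 1.5 or more had 70.3% of summits outside genes (upper end of shifts 36.5%), but they are part of the regions already counted, so this value decides nothing about the cause. Binding of PIL5-myc between genes and precipitation of open chromatin without PIL5 cannot be told apart, since no precipitation from untagged seeds was compared here, and base composition itself was not tested.

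A hypothesis that long spaces between genes hold more regions than their share of the tiling was fixed before its result was seen. The 1429 summits between genes lay in spaces with a median length of 2536 bp, below the 3050 bp of shifted summits (95% of shifts between 2770 and 3361; two-sided permutation p = 5e-04), so the prediction was not met and the spaces were shorter. For regions at 2-fold or more the median was 2444 bp (95% of shifts between 2638 and 3518; permutation p = 0.005).

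Exchanging precipitated and input DNA within arrays makes 4 arrangements of 3 arrays, too few for a share under 0.05. The real one gave 3463 enriched regions and the highest of the others 0, so 1 of 4 gave as many, and for genes with an enriched flank it was 1288 against 0 (limma; 3893 to 5976 windows and 85 to 95 flanks at an unadjusted p under 0.05 in the others). The exchange of replicate 3 is the labels' dye direction. In 20 random rotations of the arrays against each other along the tiling, limma called 0 enriched and 0 depleted regions, with a median of 16850 windows at an unadjusted p under 0.05. Rotation also removes probe effects shared by the arrays, so these counts say nothing about regions from such effects. Without signal shared by the arrays, the adjusted threshold is also stricter than on the real arrays. A count of 0 in the rotations or the other exchanges therefore sets no limit on chance regions among the 3463.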
